A study of Mus musculus with 12 samples.

How the data were processed

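RNA was sequenced from F4/80-positive endometrial cells of mice in 12 libraries, 3 in each of 4 groups (Sham, IUA, IUA with control MSC, IUA with primed MSC). The deposited table holds 1 FPKM value per gene and library for 22294 genes, computed by the authors and rounded to 2 decimals, not rescaled to a fixed total. The submitters' processing notes name fastp, HISAT2, StringTie, RSEM and DESeq2 and the build mm10, without versions. Tests for a step that whole fragments would leave between values did not recover whole reads. They were weak: on a table rebuilt from whole fragments, recovered depth ratios correlated with the true ones at only 0.369. They therefore do not show that such steps are absent. The depth is unknown, so no count test was used and no interval that needs counts is given. Genes at 0 in every library numbered 4237. Symbols stored as dates were restored for 27 genes from the gene identifier, and 25 identifiers that shared a symbol with another were kept apart. No pair of libraries held identical values.

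FPKM was analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1. Genes with FPKM of at least 1 in at least 3 libraries were kept, which left 11604. A linear model with 1 mean per group was fitted to all 12 libraries together, with an empirical Bayes variance trend, and 6 comparisons were drawn from it. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes are said to rise, fall or change. A moderated F test covered the 4 groups. Log2 changes are given with their standard error (SE) from limma and FPKM means with the SD of 3 libraries. An exact permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1. The replicate numbers in the labels do not show that libraries were paired, so no block entered the model.

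Of 45 gene lists, 43 with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over the lists of a comparison. With an estimated correlation no list passed in any comparison. The lowest adjusted p was 0.0970 for IUA against Sham, 0.131 and 0.174 for control and primed MSC against Sham, and 0.785 or more for the comparisons among the IUA groups. The rotation test fry, which does not compare a list with other genes, called 24 lists for IUA against Sham, none for control MSC against IUA, 5 for primed MSC against IUA, none for primed against control MSC, and 29 and 33 for control and primed MSC against Sham. Its lowest adjusted p was 0.334 and 0.179 in the comparisons without a call.

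Groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. By that rule the text names, for each comparison, up to 8 genes per direction with the largest log2 change among those that passed, whose groups did not overlap, and whose symbol is not a predicted, clone, immunoglobulin or T cell receptor name. It adds up to 4 members of each list described, those with the smallest p, whether or not they passed (none for lists given by their counts alone), and Adgre1, Csf1r, Cd68 and Ptprc in every group. Where fewer than 3 genes passed in a direction, the rule names the 3 of smallest p, which no comparison needed. Of the genes given by the rule, 2 are not reported here. Xist, also in the rule, was not analysed here. Which lists are described, and how many members of each, was decided after the list results were seen, to stay near 30 genes per comparison. The keratins Krt8 and Krt18 were also added after the data were seen.

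Alternatives covered pseudocounts of 0.1 and 0.5, no filter and a filter at FPKM 5, TPM, median-ratio and quantile scaling, a fit to the compared groups alone, a replicate block, array weights, robust variances, an adjusted p under 0.1, a log2 change of at least 1, leaving out each library, signatures of 100 and 500 genes, and splitting the IUA libraries between the comparisons that share them. Others were added after seeing the data: a correction for the GC content of transcripts (lowess, span 0.3), the mean of the uterine epithelium list as a covariate, both together, and the GC correction without IUA replicate 3. On simulated data with the spread of these libraries, the fit found 70 to 80 percent of genes changed by a log2 of 1 and 93 to 99 percent of those changed by 2. The same data gave 5 to 14 false calls. A list shifted by 0.5 in them, the lysosome genes, was found by camera, by camera with an estimated correlation and by fry. Simulated genes varied independently, so this does not show that the test with an estimated correlation finds such a shift in these data, where the correlation of that list was 0.347.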

Results

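Messenger RNA was measured by RNA sequencing in F4/80-positive cells, the macrophage fraction, sorted with magnetic beads from the endometrium of mice. The 12 libraries fell into 4 groups of 3. Sham mice had a sham operation. IUA mice carried a model of intrauterine adhesion, in which scar tissue closes the uterine cavity. The IUA libraries alone bear the name Matrigel, and whether it was part of the model or a carrier for the cells is not stated. If only IUA mice received it, its effect cannot be told apart from that of the model or the cells in comparisons with IUA. The remaining groups were IUA mice given mesenchymal stromal cells (MSC) from human umbilical cord, either control cells or cells primed with inflammatory cytokines. They are called control MSC and primed MSC here. The values are the authors' FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library). The FPKM of a library summed to between 505459.9 and 563751, which is not a sequencing depth, and the depth is unknown. Of 22294 genes in the table, 11604 were tested, and 7771 of these differed among the 4 groups by the moderated F test of limma. The p-values measure the spread between these samples. Genes are placed on the mouse build mm10.

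The sort antigen F4/80 is encoded by Adgre1 (chromosome 17, 57358691 to 57483527), whose level was 223 ± 29.0 FPKM in Sham, 434 ± 38.1 in IUA, 939.9 ± 101 in control MSC and 1175 ± 199.8 in primed MSC (mean ± SD, n = 3). Adgre1 rose in IUA against Sham (log2 change 0.96 ± 0.14, SE, adjusted p = 2.60e-04) and in each treated group against IUA. Csf1r, the receptor for macrophage colony-stimulating factor, was at 148 ± 16.7, 202 ± 75.0, 279 ± 13.985 and 364 ± 9.32 FPKM in the same order. Cd68, a lysosomal glycoprotein of macrophages, stood at 556 ± 100.1, 1341 ± 267, 1142 ± 61.4 and 969 ± 65.1 FPKM, and Ptprc, the leukocyte antigen CD45, at 84.6 ± 9.78, 192 ± 28.0, 178 ± 22.9 and 178 ± 6.63. The epithelial keratins Krt8 and Krt18 together made up 1.20 to 2.13 percent of a Sham library's FPKM, 0.213 to 0.744 percent in IUA, 0.203 to 0.518 percent in control MSC and 0.206 to 0.317 percent in primed MSC. Sham libraries lay apart from the other groups on the principal component that held 63.4 percent of the variance. The libraries also differed in how their values followed the GC content of the transcripts. The Spearman correlation across genes, which are not independent replicates, was -0.491 in IUA replicate 3, -0.148 and -0.184 in the other IUA libraries, and 0.145 to 0.219 in primed MSC. It lay between -0.0958 and 0.0924 in Sham and control MSC.

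**Figure D1:**
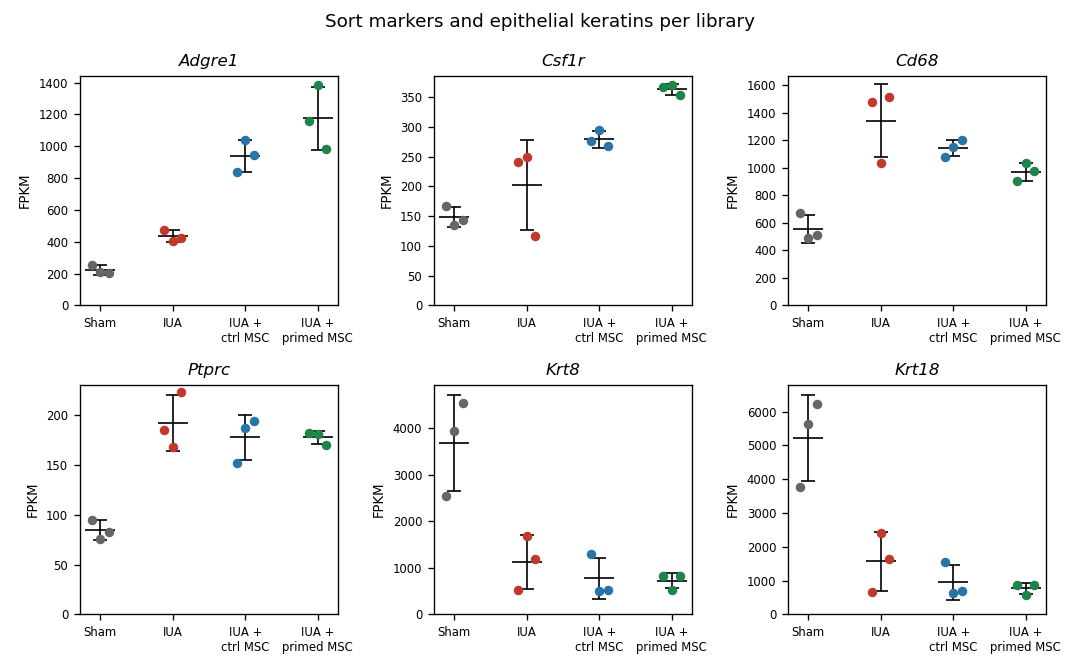
FPKM of 4 sort and leukocyte markers and of the keratins Krt8 and Krt18 in each of the 12 libraries; points are libraries, the horizontal mark is the group mean and the bar its SD (n = 3). Adgre1 was at 837 FPKM or more in every treated library and at 476 or less in every Sham and IUA library.

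The comparison of IUA with Sham asks how the adhesion model altered the sorted cells. Arg1, the arginine-degrading enzyme arginase 1 (chromosome 10, 24915221 to 24927484), rose from 5.97 ± 3.63 to 1140.2 ± 421 FPKM (SD, n = 3; log2 change 7.43 ± 0.34, adjusted p = 1.39e-07). Chil3, a secreted chitinase-like protein of alternatively activated macrophages, rose from 15.9 ± 3.06 to 2725 ± 2009 FPKM (log2 change 6.99 ± 0.54, adjusted p = 4.06e-06). Spp1, which encodes osteopontin, rose from 277 ± 30.1 to 4651 ± 975 FPKM (log2 change 4.05 ± 0.18). The acute-phase protein gene Saa3, the scavenger receptor gene Marco, coagulation factor gene F7, Ly6i and Rnase2a also rose, by log2 changes of 4.02 to 4.85. Among the genes with the strongest falls were Car12, a carbonic anhydrase (log2 change -3.26 ± 0.67), Dkk3, of a family of Wnt antagonists (-3.05 ± 0.33), and Pcx, pyruvate carboxylase (-2.95 ± 0.47). Bpifb5, Gulo, Prss28, Arc and Syn2 fell, with log2 changes between -3.59 and -3.01.

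Macrophage and monocyte genes rose together in IUA. Of the macrophage identity list, 16 of 20 measured members rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone. Its median log2 change was 0.94 (camera adjusted p = 3.82e-14; adjusted p = 0.0970 with an estimated correlation). Examples were the lysosomal protease Ctss (2.00 ± 0.10) and the lipopolysaccharide co-receptor Cd14 (1.28 ± 0.12). In the monocyte list 12 of 14 rose, as they did adjusted over the list alone, among them coagulation factor F10 (3.96 ± 0.20) and thrombospondin Thbs1 (1.62 ± 0.12; camera adjusted p = 3.05e-11; adjusted p = 0.0970 with an estimated correlation). Pro-inflammatory (M1) markers gave 15 of 20 higher and none lower, 15 higher adjusted over the list alone, with Marco (4.34 ± 0.23) and the cytokine Il1a (2.83 ± 0.20) in front (camera adjusted p = 8.72e-14; adjusted p = 0.0970 with an estimated correlation). Alternative activation (M2) markers rose as well, with 11 of 20 higher and 1 lower and the same counts adjusted over the list alone. Beside Arg1 they included the beta-glucan receptor Clec7a (2.40 ± 0.11; camera adjusted p = 1.19e-07; adjusted p = 0.0970 with an estimated correlation). The chemokine list had 12 members higher and 3 lower of 27, as it did adjusted over the list alone, with Ccl6 (2.38 ± 0.15) and Cxcl3 (2.15 ± 0.17) among those higher (camera adjusted p = 1.01e-06; adjusted p = 0.137 with an estimated correlation). In the lysosome list 16 of 23 rose and 1 fell, with the same counts adjusted over the list alone, and cathepsin gene Ctsz gained 1.54 ± 0.13 (camera adjusted p = 1.96e-12; adjusted p = 0.127 with an estimated correlation).

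Markers of other cell types and of sample quality moved with these groups. Of the uterine epithelium list, 18 of 19 members fell and 1 rose, as they did adjusted over the list alone, and the median log2 change was -1.76 (camera adjusted p = 0.00766; adjusted p = 0.741 with an estimated correlation). Pax8, a transcription factor of the female tract epithelium, changed by -2.13 ± 0.33, and Prom1, the membrane protein CD133, by -2.02 ± 0.34. In the endothelium list 14 of 15 fell over all genes and 15 adjusted over the list alone, with the endothelial adhesion molecule Esam at -1.67 ± 0.26 and the angiopoietin receptor Tek at -1.45 ± 0.24 (camera adjusted p = 0.00211; adjusted p = 0.576 with an estimated correlation). The neutrophil list ran the other way, with 7 of 11 higher over all genes and 8 adjusted over the list alone. It held the collagenase Mmp8 (2.39 ± 0.34) and the antimicrobial peptide gene Camp (2.00 ± 0.30; camera adjusted p = 3.09e-06; adjusted p = 0.176 with an estimated correlation). The B cell and plasma cell list was higher as a set, with 3 of 10 higher and 1 lower, as they were adjusted over the list alone (camera adjusted p = 0.0228; adjusted p = 0.393 with an estimated correlation). Of the immediate-early and dissociation stress genes, a sign of sample quality, 13 of 22 fell and 1 rose, with the same counts adjusted over the list alone and a median of -0.71, while the list did not pass (camera adjusted p = 0.3004). Among all 11604 tested genes 5226 fell, with a median of -0.35, so the stress list was not set apart from other genes. Fosb and Jund, transcription factors induced within minutes of a stimulus, were at -1.11 ± 0.17 and -2.50 ± 0.42.

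In all, 6517 genes changed in IUA against Sham by limma, 1291 higher and 5226 lower, and the median log2 change of all tested genes was -0.35. With libraries scaled to a common median ratio that median was -0.03, and 2532 genes were higher and 2716 lower. With the epithelial score of each library as a covariate 1156 genes changed, a setting added after seeing the data, and the score of every Sham library lay above that of every IUA library.

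Comparing control MSC with IUA asks what the unprimed cells altered. Slc13a3, a transporter of dicarboxylates (chromosome 2, 165405028 to 165473230), rose from 4.87 ± 0.629 to 74.3 ± 23.3 FPKM (SD, n = 3; log2 change 3.64 ± 0.30, adjusted p = 4.79e-04). Mmp9, a gelatinase that degrades matrix, rose from 10.2 ± 3.00 to 53.7 ± 14.2 FPKM (log2 change 2.29 ± 0.26), and Siglece, an inhibitory receptor for sialic acids, from 11.4 ± 2.33 to 46.8 ± 10.4 FPKM (log2 change 1.94 ± 0.18). Il23a, a subunit of the cytokine interleukin 23, fell from 11.4 ± 2.07 to 3.19 ± 0.745 FPKM (log2 change -1.57 ± 0.23, adjusted p = 0.0153). The serine protease genes Prss28 and Prss29 of uterine glands rose by 4.78 ± 0.71 and 4.64 ± 0.83, and Dmbt1, Agr2 and Fcrl5 rose by 2.04 to 3.38. No member of the uterine epithelium list passed beside them, over all genes or adjusted over the list alone, and its median log2 change was -0.35 (camera adjusted p = 0.0773). Ogn, a proteoglycan of the matrix, fell (log2 change -1.69 ± 0.33), as did Adh1, an alcohol dehydrogenase (-1.62 ± 0.31). Camp, Ctxn1, Cald1 and Ephx1 fell, with log2 changes between -1.50 and -0.92.

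Adgre1 was the member of the macrophage identity list that rose over all genes (1.11 ± 0.14, adjusted p = 0.00942). Adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 0.0167; adjusted p = 0.785 with an estimated correlation). The fractalkine receptor gene Cx3cr1 (0.73 ± 0.17, adjusted p = 0.0592) and the integrin gene Itgam (0.79 ± 0.22, adjusted p = 0.103) did not pass. The list of MHC class II presentation, which shows antigen to helper T cells, was lower as a set, with a median log2 change of -0.47 (camera adjusted p = 3.51e-06; adjusted p = 0.785 with an estimated correlation). None of its 9 members passed over all genes and 8 were lower adjusted over the list alone, with H2-DMb1 at -0.57 ± 0.12, H2-Ab1 at -0.59 ± 0.17 and H2-DMa at -0.43 ± 0.13. Interferon-gamma-induced genes had a median of -0.36 (camera adjusted p = 0.00110; adjusted p = 0.785 with an estimated correlation), with no member passing over all genes and 3 lower adjusted over the list alone. The interferon-induced GTPase genes Iigp1, Tgtp2 and Gbp3 were at -1.12 ± 0.26, -1.02 ± 0.27 and -0.66 ± 0.19. The smooth muscle and pericyte list, of another cell type, had a median of -0.76 with 6 of 13 lower adjusted over the list alone and none over all genes (camera adjusted p = 3.27e-05; adjusted p = 0.785 with an estimated correlation). Its members Mylk, Synpo2 and Cnn1 stood at -1.35 ± 0.37, -0.90 ± 0.26 and -1.29 ± 0.39. The dendritic cell list, of cells rich in MHC class II, was also lower, with a median of -0.38 and none of its 9 members passing over all genes or adjusted over the list alone (camera adjusted p = 0.0228; adjusted p = 0.785 with an estimated correlation). So were the lists of endometrial stroma (median -0.31, camera adjusted p = 0.0138; adjusted p = 0.785 with an estimated correlation), eosinophils (-0.65, camera adjusted p = 0.0328; adjusted p = 0.785 with an estimated correlation), mesothelium (-0.56, camera adjusted p = 0.0447; adjusted p = 0.785 with an estimated correlation) and NK cells (-0.46, camera adjusted p = 0.0486; adjusted p = 0.813 with an estimated correlation). None of their members passed over all genes, and adjusted over the list alone 2 of 15 stroma and 2 of 5 eosinophil genes were lower and none of the other 2 lists. The stroma list's mean log2(FPKM + 1) was 3.97, 2.98 and 2.88 in IUA replicates 1 to 3 and 2.74 in control MSC. For mesothelium it was 2.79, 1.20 and 1.62 in IUA and 1.31 in control MSC, so IUA replicate 1 carried much of both falls. For dendritic cells it was 2.98, 2.53 and 2.44 in IUA and 2.21, 2.18 and 2.52 in control MSC, so IUA replicate 1 carried part of that fall. The NK list was at 2.14, 1.73 and 1.72 in IUA and 0.86, 1.26 and 2.34 in control MSC, where replicate 3 lay above every IUA library. MHC class II was at 8.12, 7.67 and 7.75 in IUA and 7.26, 7.18 and 7.57 in control MSC. The tissue-resident macrophage list (median -0.34, camera adjusted p = 0.0488; adjusted p = 0.813 with an estimated correlation) and M2 markers (median -0.31, camera adjusted p = 0.0228; adjusted p = 0.785 with an estimated correlation) were lower as sets, with no member passing over all genes. Adjusted over the list alone 2 resident genes were higher and 1 lower, and 1 M2 gene was higher and 2 lower. M1 markers did not pass as a list (camera adjusted p = 0.366), and their median of 0.10 and mean of -0.09 differed in sign, the test following the mean. Within it Il23a fell, Il1a (-0.88 ± 0.20, adjusted p = 0.0589) and Il12b (-1.13 ± 0.29, adjusted p = 0.0849) did not pass, and adjusted over the list alone 2 were higher and 4 lower.

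Over all genes 99 changed in control MSC against IUA by limma, 84 higher and 15 lower. This count moved with single libraries: it was 329 without IUA replicate 1, 5 and 6 without control MSC replicates 2 and 3, and 35 to 59 without any other library except Sham replicate 1, where it was 114.

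Against IUA, primed MSC changed more genes. Tgfb3, a growth factor of the TGF-beta family (chromosome 12, 86056745 to 86079041), rose from 4.90 ± 1.39 to 27.0 ± 1.72 FPKM (SD, n = 3; log2 change 2.28 ± 0.19, adjusted p = 1.16e-04). Slc13a3 rose to 123 ± 32.1 FPKM (log2 change 4.38 ± 0.30) and Slc16a3, a lactate transporter, from 29.1 ± 20.7 to 171 ± 12.5 FPKM (log2 change 2.94 ± 0.54). Retnla, a secreted protein of alternatively activated macrophages, fell from 501 ± 379 to 38.0 ± 12.4 FPKM (log2 change -3.42 ± 0.67, adjusted p = 0.00614), and Chil3 fell (log2 change -2.34 ± 0.54, adjusted p = 0.0119). Both genes varied within IUA, where Chil3 was at 2639.7, 4774 and 759.9 FPKM in replicates 1 to 3. Xylt2, Fcrl5, Mmp9, Siglece and Dmbt1 also rose, by 2.26 to 2.98. Ccl24, a chemokine that attracts eosinophils, fell (log2 change -2.02 ± 0.41), and Rnase2a, Ear2, Serpina1e, Dcn and Efemp1 fell, with log2 changes between -2.72 and -1.88.

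Genes of macrophage identity and of the resident subset moved in different directions. Over all genes 7 of 20 identity genes rose and none fell, with Adgre1 at 1.43 ± 0.14 and the Fc receptor gene Fcgr1 at 0.95 ± 0.14 (camera adjusted p = 0.0214; adjusted p = 0.905 with an estimated correlation). Adjusted over the list alone 8 rose and 3 fell. The tissue-resident macrophage list had 6 of 13 lower and 1 higher over all genes, and 9 lower and 1 higher adjusted over the list alone. It included the lectin Fcna (-1.52 ± 0.25) and the haemoglobin scavenger receptor Cd163 (-1.26 ± 0.21; camera adjusted p = 0.00579; adjusted p = 0.905 with an estimated correlation). M2 markers had 8 of 20 lower and 2 higher, or 13 and 3 adjusted over the list alone (camera adjusted p = 0.0101; adjusted p = 0.887 with an estimated correlation). Chil4 fell (-1.26 ± 0.20) while the interleukin 4 receptor gene Il4ra rose (2.00 ± 0.29). M1 markers went both ways, 3 higher and 4 lower, over all genes and adjusted over the list alone. Among them the transcription factor gene Irf5 rose by 1.06 ± 0.18 and Il23a changed by -1.29 ± 0.23 (camera adjusted p = 0.918). Of the NF-kB targets 5 of 18 rose, also adjusted over the list alone, led by Nfkb2 (1.56 ± 0.28) and Bcl3 (0.94 ± 0.23; camera adjusted p = 0.0214; adjusted p = 0.905 with an estimated correlation). The mean log2(FPKM + 1) of these targets was 6.09, 6.03 and 5.45 in IUA replicates 1 to 3 and 6.25 in primed MSC, so IUA replicate 3 carried part of the rise. The TGF-beta signalling list did not pass (camera adjusted p = 0.331). In it 4 of 18 members rose over all genes and 5 adjusted over the list alone, among them Tgfb3 and Tgfb1 (1.39 ± 0.24). Over the alternatives the log2 change ran from 0.77 to 1.97 for Tgfb1 and from 0.89 to 1.83 for Nfkb2. For Irf5 it ran from 0.64 to 1.29 and for Bcl3 from 0.36 to 1.13. Bcl3 was no longer called under 3 of 29 alternatives. Interferon-gamma-induced genes did not pass as a list (median 0.27, camera adjusted p = 0.0536), while 4 of 22 rose and none fell, over all genes and adjusted over the list alone.

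Signs of RNA quality and of other cells moved with these groups. Of the mitochondrially encoded genes 10 of 13 fell over all genes and 11 adjusted over the list alone, with mt-Cytb at -0.75 ± 0.15 and mt-Nd2 at -0.70 ± 0.15 (camera adjusted p = 1.25e-05; adjusted p = 0.887 with an estimated correlation). In the endometrial stroma list 3 of 15 fell over all genes and 4 adjusted over the list alone, including the matrix proteoglycans Dcn (-1.97 ± 0.40) and Lum (-1.81 ± 0.46; camera adjusted p = 0.00962; adjusted p = 0.905 with an estimated correlation). Beside the falls of Ccl24, Ear2 and Rnase2a, 3 of 5 eosinophil markers fell, also adjusted over the list alone, with a median of -0.79 (camera adjusted p = 0.0424; adjusted p = 0.887 with an estimated correlation). The mesothelium list had a median of -1.02, with none of 6 lower over all genes and 5 adjusted over the list alone (camera adjusted p = 0.0214; adjusted p = 0.905 with an estimated correlation). IUA replicate 1 was the highest IUA library for the stroma and mesothelium lists and carried part of both falls. The T cell list had 3 of 9 lower, over all genes and adjusted over the list alone, among them the costimulatory receptor gene Cd28 (-0.98 ± 0.20) and the receptor constant gene Trbc1 (-1.07 ± 0.28; camera adjusted p = 0.0101; adjusted p = 0.887 with an estimated correlation). The GC trend also ran in opposite directions in IUA and primed MSC libraries. By limma 2219 genes changed, 1410 higher and 809 lower. Without IUA replicate 3 the count was 1333, and without primed MSC replicate 1, 2 or 3 it was 1154, 1254 or 1369.

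**Figure D2:**
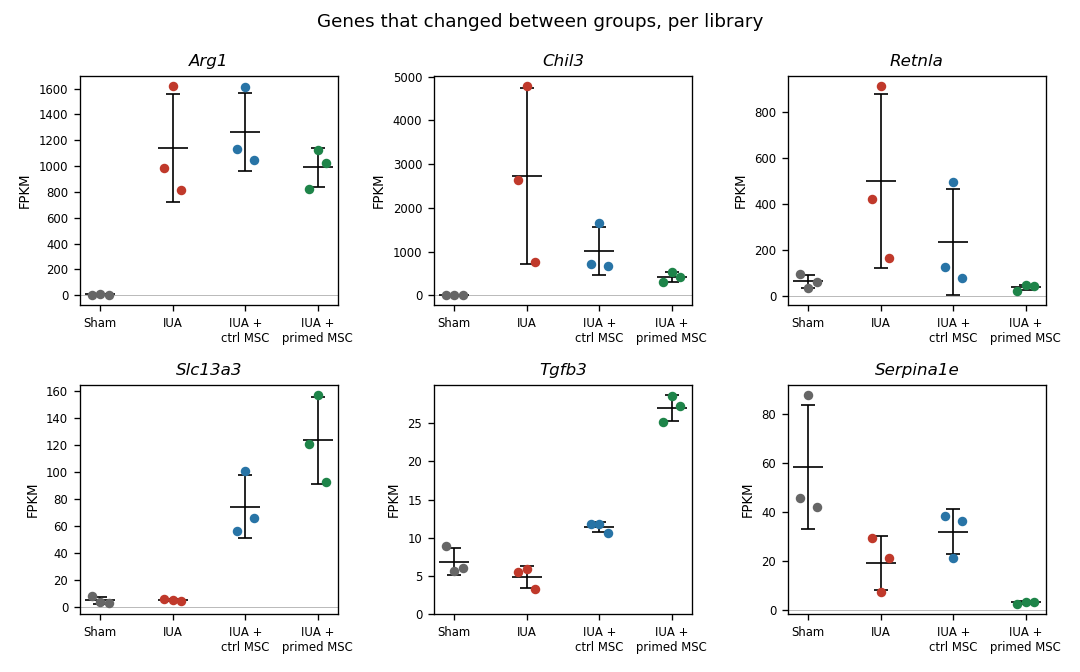
FPKM of Arg1, Chil3, Retnla, Slc13a3, Tgfb3 and Serpina1e in each of the 12 libraries; points are libraries, the horizontal mark is the group mean and the bar its SD (n = 3). Tgfb3 was at 25.2 FPKM or more in every primed MSC library and at 11.9 or less in the other libraries.

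The direct comparison of primed with control MSC asks what priming added. Tgfb3 was at 27.0 ± 1.72 FPKM in primed and 11.4 ± 0.710 FPKM in control MSC (SD, n = 3; log2 change 1.17 ± 0.19, adjusted p = 0.04996). Pxn, the focal adhesion protein paxillin (chromosome 5, 115506676 to 115555987), rose by 1.40 ± 0.20 (adjusted p = 0.0342) and Hdac5, a histone deacetylase, by 1.09 ± 0.15 (adjusted p = 0.0283). Map3k11, Jak3, Dctn1 and Epb41 rose by 0.91 to 1.22. Serpina1e, of the alpha-1-antitrypsin family, fell (log2 change -3.02 ± 0.42, adjusted p = 0.0304), and Pinlyp, Cwh43 and S100a10 fell, with log2 changes of -2.13 ± 0.27, -1.28 ± 0.21 and -0.68 ± 0.10. Pinlyp was at 0.503 ± 0.613 FPKM in primed and 5.35 ± 1.17 in control MSC, and Cwh43 at 0.463 ± 0.208 and 2.57 ± 0.701. Both lay near the floor, and over the alternatives their log2 changes ran from -3.63 to -1.96 and from -2.27 to -1.13. The GC content of the Pxn, Jak3 and Hdac5 transcripts was 60.6, 60.7 and 60.9 percent, against 53.0 percent for Tgfb3. After a GC correction, a setting added after seeing the data, 17 genes changed and these 3 were still called, with log2 changes of 1.22, 0.98 and 0.90, while Dctn1 did not pass (0.84).

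Interferon-gamma-induced genes were higher in primed MSC as a set, with a median log2 change of 0.60 (camera adjusted p = 1.00e-13; adjusted p = 0.826 with an estimated correlation). Over all genes 1 of 22 passed, and adjusted over the list alone 12 rose. The chemokine Cxcl9 (1.19 ± 0.20, adjusted p = 0.0504), Serpina3g (1.17 ± 0.20, adjusted p = 0.0541) and Irf8 (0.57 ± 0.14, adjusted p = 0.139) stood next in rank. MHC class I presentation had a median of 0.22 with 1 of 16 higher adjusted over the list alone and none over all genes (camera adjusted p = 1.06e-04; adjusted p = 0.826 with an estimated correlation). The peptide transporter genes Tap1 and Tap2 were at 1.06 ± 0.25 and 0.72 ± 0.27, and the immunoproteasome genes Psmb9 and Psmb8 at 0.52 ± 0.20 and 0.32 ± 0.13. The MHC class II list (median 0.21, camera adjusted p = 0.00821; adjusted p = 0.827 with an estimated correlation) and NF-kB targets (median 0.26, camera adjusted p = 0.00101; adjusted p = 0.827 with an estimated correlation) were higher as sets with no member passing over all genes, and adjusted over the list alone 2 class II genes and no NF-kB target were higher. The tissue-resident macrophage list was lower (median -0.56, camera adjusted p = 6.48e-04; adjusted p = 0.826 with an estimated correlation), with no member passing over all genes and 4 lower adjusted over the list alone. Timd4, Fcna, Folr2 and Cd163 were at -0.85 ± 0.21, -0.86 ± 0.25, -0.62 ± 0.18 and -0.58 ± 0.21. M2 markers did not pass as a list (camera adjusted p = 0.0584). None of the M2 genes passed over all genes, 2 were higher and 4 lower adjusted over the list alone, and Chil4, Il4ra, Tgfb1 and Retnla stood at -1.16 ± 0.20, 1.00 ± 0.29, 0.78 ± 0.24 and -2.20 ± 0.67. Mitochondrially encoded genes, a sign of RNA quality, were lower in the same libraries (median -0.42, camera adjusted p = 5.68e-09; adjusted p = 0.826 with an estimated correlation). In that list 10 of 13 were lower adjusted over the list alone and none over all genes, with mt-Nd3, mt-Co2, mt-Nd2 and mt-Nd6 at -0.82 ± 0.19, -0.47 ± 0.11, -0.48 ± 0.15 and -0.59 ± 0.18. The oxidative phosphorylation list, of nuclear genes, was lower as well (median -0.14, camera adjusted p = 0.00191, and adjusted p = 0.827 with an estimated correlation). None of its 27 members passed over all genes or adjusted over the list alone. Whether the mitochondrial fall reflects RNA quality was not tested. Immediate-early and dissociation stress genes, another sign of sample quality, were higher as a set (median 0.06, mean 0.24, camera adjusted p = 0.0228; adjusted p = 0.827 with an estimated correlation), with none of 22 passing over all genes and 1 higher adjusted over the list alone. The T cell list was lower (median -0.36, camera adjusted p = 0.0216; adjusted p = 0.826 with an estimated correlation), with none of 9 passing over all genes and 2 lower adjusted over the list alone.

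By limma 13 genes changed, 9 higher and 4 lower, and 6 of the 9 had an adjusted p of 0.04996. Without any 1 of the 6 libraries compared it was 0 to 2, without Sham replicates 2 and 3 it was 4 and 6, and without IUA replicate 3, a library outside the comparison that enters the shared spread, it was 233. It was 0 by limma with no filter on low values, and 1496 genes had an unadjusted p under 0.05 with the filter.

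**Figure D3:**
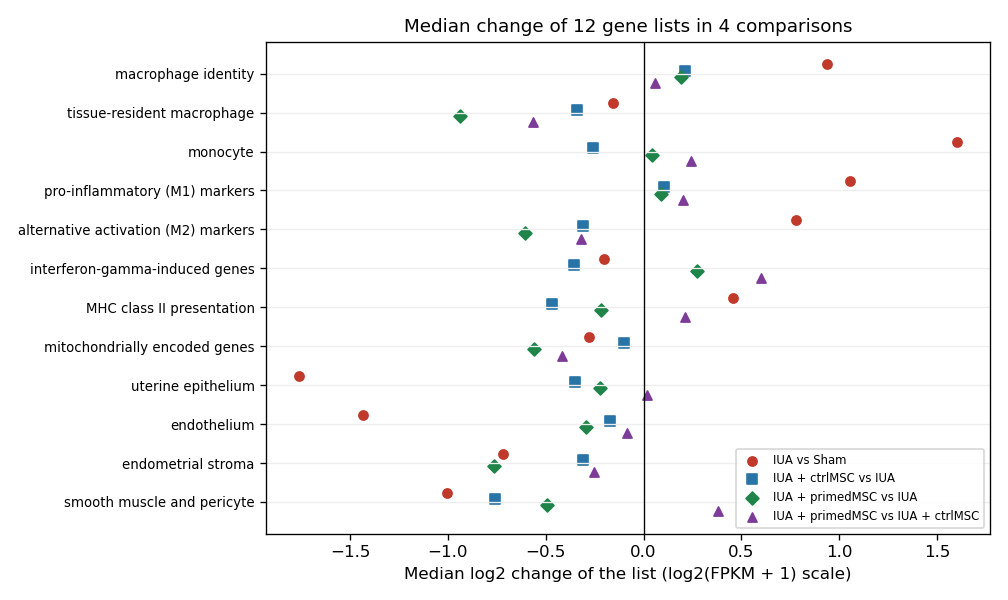
Median log2 change, on the log2(FPKM + 1) scale, of 12 gene lists (vertical axis) in 4 comparisons, each marked by its own symbol; a point is the median over the measured members of a list. Interferon-gamma-induced genes had a median of 0.60 in primed against control MSC.

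Both treated groups were also compared with Sham, which asks how far the treated cells stood from cells without adhesion. Arg1 was again far above Sham, at 7.62 ± 0.34 on the log2 scale in control MSC and 7.28 ± 0.34 in primed MSC (SE, n = 3 per group). Saa3 rose by 5.87 ± 0.35 and 5.02 ± 0.35, Chil3 by 5.81 ± 0.54 and 4.65 ± 0.54, and Fpr1, a receptor for formyl peptides, by 4.99 ± 0.28 and 4.67 ± 0.28. In control MSC Marco, Cxcl13, S100a8 and Dmbt1 rose by 4.41 to 4.82, and in primed MSC Ly6i, Sirpb1c, Slc13a3 and Tarm1 by 4.09 to 4.83. Gulo, Calb1 and the glucose transporter gene Slc2a3 fell in both groups, with log2 changes of -4.04 ± 0.59, -3.45 ± 0.50 and -3.44 ± 0.46 in control MSC and -4.04 ± 0.59, -3.56 ± 0.50 and -3.71 ± 0.46 in primed MSC. Il17rb, Gstm7, Cxcl15, Pcx and Sbspon fell in control MSC, with log2 changes between -3.48 and -3.28. Wfdc3, Cyp3a59, Serpina1e, Angptl7 and Cd209a fell in primed MSC, with log2 changes between -4.25 and -3.66. By limma 6592 genes changed in control MSC, 1632 higher and 4960 lower, and 6903 in primed MSC, 1684 higher and 5219 lower. With libraries scaled to a common median ratio, which centres the changes, 2887 were higher and 2952 lower in control MSC and 3083 and 3091 in primed MSC. All comparisons with Sham share the same 3 Sham libraries. Of the macrophage identity list 18 and 18 of 20 members rose in control and primed MSC, or 18 and 19 adjusted over the list alone, and 1 fell in primed MSC (camera adjusted p = 8.78e-15 and 9.73e-15; adjusted p = 0.131 with an estimated correlation for control MSC and adjusted p = 0.174 with an estimated correlation for primed MSC). The uterine epithelium list had 18 of 19 members lower in control MSC and 18 in primed MSC, as it did adjusted over the list alone (camera adjusted p = 0.00133 and 0.00342; adjusted p = 0.677 with an estimated correlation for control MSC and adjusted p = 0.603 with an estimated correlation for primed MSC). In the same order, 10 and 11 of 15 endometrial stroma, 13 and 12 of 13 smooth muscle and pericyte and 15 and 15 of 15 endothelium genes fell, and 7 and 6 of 11 neutrophil genes rose, as they did adjusted over the list alone. These lists passed in both groups by camera, and with an estimated correlation their lowest adjusted p was 0.210 and 0.269. The mitochondrially encoded genes fell in 12 of 13 members in primed MSC, 13 adjusted over the list alone (camera adjusted p = 0.00185; adjusted p = 0.603 with an estimated correlation), and in 7 in control MSC, 7 adjusted over the list alone, where the list did not pass (camera adjusted p = 0.204). In control MSC 8 of 9 mast cell genes fell, 9 adjusted over the list alone (camera adjusted p = 0.0313; adjusted p = 0.476 with an estimated correlation), and 4 of 10 B cell and plasma cell genes rose and 2 fell, as they did adjusted over the list alone (camera adjusted p = 0.0233; adjusted p = 0.476 with an estimated correlation). With the epithelial score as a covariate 1021 and 1798 genes changed.

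A further question is whether treatment moved genes back toward Sham. Of the genes called in both comparisons, 895 changed in opposite directions in IUA against Sham and in primed MSC against IUA, and 453 in the same direction. If the calls were independent, 725 opposite calls would be counted. The IUA libraries enter both comparisons with opposite sign, so opposite changes arise without any effect of treatment. The covariance of the log2 changes across genes was -0.0288. In 100 simulated sets of unchanged groups it was -0.0255 on average, with 95 percent of the sets between -0.0561 and 0.00295. For control MSC 26 genes changed in opposite directions and 27 in the same, with 39.5 opposite calls if independent. There the covariance was 0.00590, just above the -0.0578 to 0.00540 that held 95 percent of the simulated sets, so on the side away from a return toward Sham. The correlation across genes was 0.0232, within the -0.827 to 0.204 of those sets. The simulated sets held no difference between groups, while 6517 genes changed in IUA against Sham. With larger changes the same covariance gives a weaker correlation, so a correlation within its range decides nothing here. The covariance left its range only narrowly. Both treatments changed 92 genes in the same direction against IUA, where 11.3 would be counted if the calls were independent. Leaving out 1 library gave 5 to 310 of these, 0 to 114 opposite calls for control MSC and 503 to 1072 for primed MSC. The IUA libraries enter both of these comparisons with the same sign. The log2 changes correlated across genes at 0.794, within the 0.0336 to 0.829 that held 95 percent of the simulated sets, while their covariance of 0.133 lay above the 0.00132 to 0.0536 of those sets. In primed against control MSC, which shares no library with IUA against Sham, the genes higher in IUA had a median log2 change of -0.06 (camera adjusted p = 0.125). The genes lower in IUA had a median of 0.01, and the remaining genes -0.06 (camera adjusted p = 0.00942; adjusted p = 0.688 with an estimated correlation). The log2 changes of the paired comparisons correlated across genes at -0.159, and 95 percent of the simulated sets lay between -0.591 and 0.562. Their covariance of -0.0347 lay below the -0.0292 to 0.0315 of those sets, on the side of a return toward Sham. As the simulated sets held no difference between IUA and Sham, neither range decides whether genes moved back.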

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

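The tests of the authors' normalization, of the share of macrophages and other cells, of epithelial cells in the Sham sort, of IUA replicate 3 and of T and NK cells were chosen only after the result was seen. The GC correction and the epithelial covariate were also settings added after seeing the data.

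A difference between groups drew attention to the genes below, whose changes against IUA differed between primed and control MSC by limma (n = 3 per group). The log2 differences were 1.40 for Pxn, 1.22 for Map3k11, 1.17 for Tgfb3, 1.16 for Jak3 and 1.09 for Hdac5. Those of Dctn1, Epb41 and Snx18 were 1.00, 0.91 and 0.78. On the lower side S100a10 was at -0.68, Cwh43 at -1.28, Pinlyp at -2.13 and Serpina1e at -3.02. Cwh43 and Pinlyp lay near the floor in primed MSC, at 0.463 and 0.503 FPKM. The 6 libraries compared make 10 splits of 3 against 3, too few for a share under 0.05, and the real split gave 13 genes against at most 0 in the others (1 of 10).

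In IUA against Sham more genes fell than rose, and markers of other cells moved with macrophage genes. The authors' normalization cannot be told apart from a true imbalance: scaling to a common median ratio gave a share of higher calls of 48.2 percent, but this scaling centres the changes by construction. A purer macrophage sort alone would lower the lists of all other cell types together. Of 13 lists, 5 lay above the median of all genes (-0.35) by more than the SE of their mean and 6 below. Of the 5, 4 had members called both ways, and the T cell list was itself at -0.18. The neutrophil list rose in 7 members and fell in none (1 list), but the monocyte list rose too. Of the genes that rose, 8.68 percent did so by over 1 log2 unit beyond the macrophage list's median of 0.94. Ctss, a member of that list, did so as well. These values therefore do not settle how far a purer sort contributed. Epithelial cells in the Sham sort cannot be told apart from the operation: the covariate left 17.7 percent of the number of calls, but the scores of Sham and IUA libraries do not overlap. Krt18 and Krt8, which an F4/80 sort should leave out, stood at 5212 ± 1275 and 3672 ± 1031 FPKM in Sham and 1568 ± 883 and 1131 ± 579 in IUA (SD, n = 3), and 1 of the 19 list members is also in another list; an effect of the adhesion model stays open beside it.

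In primed MSC against IUA 2219 genes changed, while GC trends and IUA replicate 3 differed between the groups. After the GC correction the number of calls was 93.1 percent of 2219, with 1608 genes called in both, which argues against GC content as the whole source. With the epithelial covariate it was 116.9 percent, with 2184 in both, and without IUA replicate 3 it was 60.1 percent, with 1254 in both. None of these accounts for all of the calls, though the count was 2560, 2106 and 1333 without IUA replicate 1, 2 and 3 and 1154 to 1369 without 1 primed MSC library, so within IUA the larger drop was particular to replicate 3. An effect of the primed cells may underlie the rest, as a hypothesis.

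Interferon-gamma-induced genes were higher in primed than control MSC by a median log2 of 0.60, a call lost with an estimated correlation (adjusted p = 0.826 with an estimated correlation), from medians of 0.27 in primed MSC against IUA, which did not pass (camera adjusted p = 0.0536), and -0.36 in control MSC against IUA. After the GC correction the median was 0.62 ± 0.18 (SE, n = 3), which argues against GC content. The SE set beside each list's median here is that of the difference in the list's mean per library. The macrophage identity list was at 0.0606 ± 0.0602, below the change of the interferon list, which argues against a larger macrophage share. T and NK cells, a source of interferon-gamma that an F4/80 sort should leave out, stay open: the NK list, the higher of the 2, was at -0.19 ± 0.45, the T cell list at -0.36 ± 0.18 spoke against more T cells but held genes near the floor, and their most abundant genes Cd28 and Nkg7 were at 2.32 ± 0.503 and 5.29 ± 1.24 FPKM in primed and 3.13 ± 0.663 and 10.6 ± 9.52 in control MSC. Priming may have raised these genes (4 of 22 rose against IUA and none fell) or control cells lowered them (none of 22 passed against IUA, camera adjusted p = 0.00110; adjusted p = 0.785 with an estimated correlation), both as hypotheses. The rise against IUA rested largely on primed MSC replicate 1. There the interferon list's mean log2(FPKM + 1) was 5.46, against 4.94 and 4.98 in replicates 2 and 3, 4.85 in IUA and 4.48 in control MSC.

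The 10 splits of 6 libraries were too few for a share under 0.05 in every pair of groups. In the number of genes, 1 split, the real one, was as large in each comparison. The real values and the highest of the others were 6517 and 0 for IUA against Sham, 99 and 98 for control MSC against IUA and 2219 and 0 for primed MSC against IUA. They were 6592 and 0 for control MSC against Sham and 6903 and 0 for primed MSC against Sham. For the number of gene lists, 5 splits were as large for IUA against Sham (21 real, 25 highest other), 5 for control MSC against IUA (16, 21) and 9 for primed MSC against IUA (12, 28). They were 10 for primed against control MSC (9, 17), 3 for control MSC against Sham (23, 27) and 2 for primed MSC against Sham (25, 25). The list calls with a preset correlation therefore arose in arbitrary groupings too. Of the splits of primed and control MSC, 7 gave the genes higher in IUA a camera p as small (0.125 real, 1.79e-21 smallest other) and 6 the genes lower in IUA (0.00471 real, 2.16e-21 smallest other).

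Among 100 drawn splits of all libraries, the real one included, 1 gave as many genes differing among the 4 groups (7771 real, 7091 highest other). That share is under 0.05, but the test covers the 4 groups together and does not show that the IUA groups differ from each other. A correlation as far from 0 as -0.159 arose in 67 of 100 (0.159 real size, 0.807 highest other). These draws mix Sham libraries into the other groups, so the difference of Sham from them can produce large correlations. The share therefore cannot decide whether chance gave this value, and chance was not excluded. The covariance of this pair, -0.0347, lay below the -0.0292 to 0.0315 of simulated unchanged groups. Opposite calls were as many in 3 of 100 for control MSC (26 real, 5287 highest other) and in 3 of 100 for primed MSC (895 real, 4732 highest other). These shares are under 0.05 but do not show a return toward Sham, as the 26 lay below the 39.5 of independent calls. The covariance for control MSC lay just above the range of simulated unchanged groups. Its correlation lay within their range, which decides nothing, as those groups held no difference between IUA and Sham. For primed MSC the covariance lay within the range of such groups. Calls in the same direction by both treatments were as many in 1 of 100 (92 real, 15 highest other).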

How the results depend on the processing

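Results were recomputed under each alternative, and the GC correction, the epithelial covariate, both together and the GC correction without IUA replicate 3 were chosen after seeing the data. Of the genes that the naming rule gave as changed, 22 of 36 in IUA against Sham, 3 of 17 in control MSC against IUA, 25 of 33 in primed MSC against IUA and 0 of 12 in primed against control MSC passed under every alternative run, and none of those called turned direction. Where a replicate was left out, the model pooled the spread over all groups, and a lone IUA library in a split was assumed to vary like the other groups. Fitting the compared groups alone met genes with no variance between libraries. Depth is unknown, so what it limits cannot be given. The cause was not tested for the values below, except that stricter filters and fewer libraries leave fewer genes or samples by construction.

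Without a filter on low values, the values were 29 genes (26 higher and 3 lower) in control MSC against IUA, 0 genes (0 higher and 0 lower) in primed against control MSC, 16 lists in primed against control MSC and 7 opposite calls of control MSC. Without a filter on low values, the other values were 27 calls in the same direction by both treatments. With a filter at FPKM 5, the values were 5 genes (3 higher and 2 lower) in primed against control MSC, 3299 lower genes in control MSC against Sham and 9 lists in control MSC against IUA. With a pseudocount of 0.1, the values were 4 genes (2 higher and 2 lower) in primed against control MSC. With a pseudocount of 0.5, the values were 5 genes (2 higher) in primed against control MSC. With median-ratio scaling, the values were 2532 higher and 2716 lower genes in IUA against Sham, 55 genes (40 higher) in control MSC against IUA, 2887 higher and 2952 lower genes in control MSC against Sham and 3083 higher and 3091 lower genes in primed MSC against Sham. With median-ratio scaling, the other values were a median of -0.0315 for genes higher in IUA (now past the threshold), 11 opposite calls of control MSC and 51 calls in the same direction by both treatments. With quantile normalization, the values were 2594 higher and 2645 lower genes in IUA against Sham, 2971 higher and 2845 lower genes in control MSC against Sham and 3140 higher and 3063 lower genes in primed MSC against Sham. Fitting the compared groups alone, the values were 16 genes (12 higher and 4 lower) in control MSC against IUA, 1343 genes (827 higher and 516 lower) in primed MSC against IUA, 207 genes (150 higher and 57 lower) in primed against control MSC and 5 opposite calls of control MSC. Fitting the compared groups alone, the other values were 443 opposite calls of primed MSC and 11 calls in the same direction by both treatments. With a replicate block, the values were 43 genes (40 higher and 3 lower) in control MSC against IUA, 0 genes (0 higher and 0 lower) in primed against control MSC, 14 lists in primed against control MSC and 13 opposite calls of control MSC. With a replicate block, the other values were 39 calls in the same direction by both treatments. With array weights, the values were 9 lower genes in control MSC against IUA, 388 genes (243 higher and 145 lower) in primed against control MSC, 15 lists in primed against control MSC and a median of -0.0603 for genes higher in IUA (now past the threshold). With robust variances, the values were 20 genes (7 lower) in primed against control MSC. At an adjusted p under 0.1, the values were 412 genes (304 higher and 108 lower) in control MSC against IUA, 1432 lower genes in primed MSC against IUA, 46 genes (34 higher and 12 lower) in primed against control MSC and 16 lists in primed against control MSC. At an adjusted p under 0.1, the other values were a median of -0.0567 for genes higher in IUA (now past the threshold), 151 opposite calls of control MSC, 1370 opposite calls of primed MSC and 372 calls in the same direction by both treatments. At a log2 change of at least 1, the values were 2159 genes (427 higher and 1732 lower) in IUA against Sham, 39 genes (32 higher and 7 lower) in control MSC against IUA, 494 genes (350 higher and 144 lower) in primed MSC against IUA and 2492 genes (546 higher and 1946 lower) in control MSC against Sham. At a log2 change of at least 1, the other values were 2692 genes (624 higher and 2068 lower) in primed MSC against Sham, 3405 genes differing among the 4 groups, 7 opposite calls of control MSC and 146 opposite calls of primed MSC. At a log2 change of at least 1, the other values were 32 calls in the same direction by both treatments. For camera with an estimated correlation, the values were 0 lists in IUA against Sham, 0 lists in control MSC against IUA, 0 lists in primed MSC against IUA and 0 lists in primed against control MSC. For camera with an estimated correlation, the other values were 0 lists in control MSC against Sham, 0 lists in primed MSC against Sham and a median of 0.00868 for genes lower in IUA (no longer past the threshold). By fry, the values were 0 lists in control MSC against IUA, 5 lists in primed MSC against IUA, 0 lists in primed against control MSC and a median of 0.00868 for genes lower in IUA (no longer past the threshold). With signatures of 100 genes, the values were a median of -0.14 for genes higher in IUA (now past the threshold). With IUA replicate 1 alone in the treatment comparison, the values were 0 opposite calls of control MSC and 84 opposite calls of primed MSC. With IUA replicate 2 alone in it, the values were 0 opposite calls of control MSC and 69 opposite calls of primed MSC. With IUA replicate 3 alone in it, the values were 548 opposite calls of control MSC. After the GC correction, the values were 23 lower genes in control MSC against IUA. Given the epithelial covariate, the values were 1156 genes (376 higher and 780 lower) in IUA against Sham, 181 genes (128 higher and 53 lower) in control MSC against IUA, 20 genes (7 lower) in primed against control MSC and 1021 genes (389 higher and 632 lower) in control MSC against Sham. Given the epithelial covariate, the other values were 1798 genes (546 higher and 1252 lower) in primed MSC against Sham, 2703 genes differing among the 4 groups, 246 opposite calls of primed MSC and 165 calls in the same direction by both treatments. Given both GC correction and covariate, the values were 1482 genes (401 higher and 1081 lower) in IUA against Sham, 181 genes (127 higher and 54 lower) in control MSC against IUA, 21 genes (14 higher and 7 lower) in primed against control MSC and 1258 genes (432 higher and 826 lower) in control MSC against Sham. Given both GC correction and covariate, the other values were 2209 genes (577 higher and 1632 lower) in primed MSC against Sham, 2803 genes differing among the 4 groups, 270 opposite calls of primed MSC and 160 calls in the same direction by both treatments. Leaving out IUA replicate 3 with GC correction, the values were 31 genes (29 higher and 2 lower) in control MSC against IUA, 1065 genes (680 higher and 385 lower) in primed MSC against IUA, 119 genes (82 higher and 37 lower) in primed against control MSC and a median of -0.0233 for genes lower in IUA (no longer past the threshold). Leaving out IUA replicate 3 with GC correction, the other values were 8 opposite calls of control MSC, 389 opposite calls of primed MSC and 30 calls in the same direction by both treatments.

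Leaving out each library in turn gave 5 to 329 genes in control MSC against IUA, 5 to 255 higher genes in control MSC against IUA, 0 to 74 lower genes in control MSC against IUA and 1154 to 2560 genes in primed MSC against IUA. Over the same 12 fits the ranges were 860 to 1508 higher genes in primed MSC against IUA, 294 to 1052 lower genes in primed MSC against IUA, 6 to 17 lists in primed MSC against IUA and 0 to 233 genes in primed against control MSC. The lowest and highest values were 0 to 183 higher genes in primed against control MSC, 0 to 50 lower genes in primed against control MSC, 9 to 18 lists in primed against control MSC and a median of -0.10 to -0.0280 for genes higher in IUA. Further ranges were a median of -0.0364 to 0.0862 for genes lower in IUA, 0 to 114 opposite calls of control MSC, 503 to 1072 opposite calls of primed MSC and 5 to 310 calls in the same direction by both treatments. The test of the genes higher in IUA changed direction without control MSC replicate 2 and without primed MSC replicate 3, while the median stayed negative.

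For lists, a turn is in the direction of the test, while the value given is the median log2 change of the list. The list of uterine epithelium in IUA against Sham turned, with values of -0.14 with epithelial score as a covariate and -0.0476 with the GC correction and epithelial score as a covariate. The score is the mean of this same list, so the covariate removes the list's difference by construction and the turn carries no information. The list of pro-inflammatory (M1) markers in control MSC against IUA turned, with a value of 0.0170 to 0.14 over the libraries left out in turn, the turn being without control MSC replicate 1. Ptprc in control MSC against IUA turned, with values of 0.0426 with the GC correction and no IUA replicate 3 and -0.20 to 0.00230 over the libraries left out in turn, the turn being without IUA replicate 3 and control MSC replicate 1. The list of pro-inflammatory (M1) markers in primed MSC against IUA turned, with values of -0.0329 with a filter at FPKM 5, 0.0884 with the compared groups alone, 0.13 with array weights and 0.0248 to 0.14 over the libraries left out in turn, the turn being without IUA replicate 3 and primed MSC replicate 1. Ptprc in primed MSC against IUA turned, with values of 0.0471 with GC correction, 0.0129 with the GC correction and epithelial score as a covariate, 0.10 with the GC correction and no IUA replicate 3 and -0.19 to 0.01004 over the libraries left out in turn, the turn being without IUA replicate 3. Ptprc in primed against control MSC turned, with values of -0.0319 with array weights and -0.10 to 0.0748 over the libraries left out in turn, the turn being without control MSC replicate 1, primed MSC replicate 1 and primed MSC replicate 2.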

Other observations

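These gene groups were picked for description after the list results were seen. Inflammasome genes rose in IUA against Sham, 7 of 11 over all genes and 7 adjusted over the list alone (camera adjusted p = 4.17e-08; adjusted p = 0.0970 with an estimated correlation). Mefv, which encodes pyrin, was at 1.95 ± 0.16 (log2 change ± SE, n = 3 per group), Gsdmd, the pore-forming gasdermin D, at 1.05 ± 0.13 and Pycard, the adaptor ASC, at 1.62 ± 0.20. Of the cholesterol biosynthesis genes 15 of 20 fell, over all genes and adjusted over the list alone, while the list did not pass (camera adjusted p = 0.0681). Lss, lanosterol synthase, was at -1.75 ± 0.23 and Pmvk, phosphomevalonate kinase, at -1.43 ± 0.21. Type I interferon-stimulated genes had 14 of 26 lower and 3 higher, also adjusted over the list alone. Their median of -0.55 and mean of -0.39 were negative while the test against other genes pointed up (camera adjusted p = 0.782). Among all 11604 tested genes 5226 fell in this comparison, with a median of -0.35.

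In primed MSC against IUA 4 of 19 glycolysis genes rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0101; adjusted p = 0.905 with an estimated correlation). The hexokinase gene Hk3 was at 1.36 ± 0.21, the lactate transporter gene Slc16a3 at 2.94 ± 0.54, pyruvate kinase gene Pkm at 0.85 ± 0.20 and hexokinase gene Hk2 at -0.54 ± 0.16. The list was also higher in control MSC against IUA, by a median of 0.34 with no member passing over all genes or adjusted over the list alone (camera adjusted p = 0.0138; adjusted p = 0.785 with an estimated correlation). In primed against control MSC it did not pass (camera adjusted p = 0.242). The list's mean log2(FPKM + 1) was 6.22, 6.42 and 5.77 in IUA replicates 1 to 3. It was 6.45 in control and 6.59 in primed MSC, so IUA replicate 3 carried part of both rises.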
